A study of Phaeodactylum tricornutum with 12 samples.

How the data were processed

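RNA was measured in 12 cultures of the marine diatom Phaeodactylum tricornutum, 4 each at 10, 20 and 26.5 °C, by sequencing strand-specific libraries made from total RNA after depletion of ribosomal RNA. Per the labels, the cultures had grown semi-continuously for more than 10 generations at their temperature, in continuous light, and were harvested in exponential growth. The sample labels give the warmest temperature as 26 and the treatment protocol gives 26.5 °C; the second value is used throughout. The letters A to G name the replicate cultures, which the labels call biological replicates.

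The deposited files hold raw counts, 1 file per library, as whole numbers of reads per gene for 10395 genes, followed by 5 summary lines that name no gene. The submitters' processing notes name TopHat2 2.1.2, Bowtie2 2.3.4.1, Picard and HTSeq. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. The files hold between 8666290 and 12743768 reads per library over all lines, of which 340541 to 570631 (3.69 to 5.46%) were assigned to genes. Reads in no annotated gene made up 84.7 to 89.4%, and reads without a unique position 6.70 to 9.89%. Ambiguous reads made up at most 0.00449%. The median gene had 12 reads per library. The strand-specific library kit and the low share of assigned reads leave open whether the counting took the strand of the transcripts or the opposite strand, and the count files cannot settle it. Values are therefore given as reads assigned to a gene. Reads without a unique position were not counted for any gene, so the counts of genes with near-identical copies are less certain.

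All 10395 identifiers matched the reference gene table of assembly ASM15095v2, which was used for names and for neighbouring genes only. Of the counted genes, 724 had a symbol of their own, and 609 of these were among the genes tested. The table gives no products and no strand.

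Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed by edgeR's filterByExpr with the temperature groups, which left 6800 genes, and libraries were scaled by TMM factors. All 12 libraries entered 1 quasi-likelihood fit with temperature as the only term, which left 9 residual degrees of freedom. With edgeR's quasi-likelihood F test 3 contrasts were tested: 10 against 20 °C, 26.5 against 20 °C, and 26.5 against 10 °C, the last being the test of the difference between the first 2. P values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p below 0.05. The SE given with a log2 fold change was derived from the test, as its absolute value divided by the square root of the F statistic. CPM are counts scaled to a common library size with the TMM factors and refer to reads assigned to genes; group values are means ± SD of 4 libraries. Principal components and correlations between libraries used log2 CPM with a prior count of 2.

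Gene lists were fixed before the data were examined, as patterns to be matched to gene symbols and product names; only symbols could be matched. Of 38 lists, 24 matched no gene and 6 held at least 5 tested genes, the minimum for a test: light-harvesting proteins, chaperones, DNA replication, histones, cell cycle and vesicle traffic. Each was tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the 6 lists, and again with the correlation estimated for each list. The number of members called was counted over all genes and adjusted over the list alone. A second set of 41 lists, 39 of them testable, was written from the reference symbols after the symbols and the counts of the most abundant genes had been seen, and before any fold change was computed.

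The genes named were chosen by a rule fixed before the data were examined: for each comparison against 20 °C, the 8 largest rises and the 8 largest falls among called genes with a symbol, a mean CPM of at least 5 and no overlap between the CPM of the 2 groups. For each of the 6 lists the rule adds up to 3 called members per direction. Fold changes between 10 and 26.5 °C are given for genes named by this rule. HSP20, HSF1, HSF3 and H3.3, and HSF2 and CDKA1 in the comparison for which the rule does not name them, were added after their values were seen, as were the genes whose fold changes at both temperatures are set side by side.

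To judge the genes called in both comparisons, which share the 20 °C libraries, 50 data sets were simulated in which all 12 libraries were drawn from the 20 °C means with the estimated dispersions and the 20 °C libraries kept their own spread. A first version of this simulation left out the sampling error of the shared libraries and was replaced. The 4 libraries at 20 °C were also parted into 2 and 2 in all 6 ways, so that the comparisons shared no library.

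The fit was tested on simulated data with known changes among 6210 genes that passed the filter. It recovered 34.0% of the 2-fold and 87.6% of the 4-fold changes between 10 and 20 °C, and 35.2% and 90.4% of those between 26.5 and 20 °C. Of its calls, 1.69% and 2.5% were genes without a change. The list test was tested in 10 simulations in which the histone list alone was raised 2-fold at 10 °C. It was called in 10 of 10. With the changed genes drawn outside the lists, 0 of 48 unchanged lists were called at 10 °C and 0 of 58 at 26.5 °C, and with the changed genes drawn from all genes, so that lists could hold some, 2 of 48 and 0 of 58 were called. The simulated genes were independent of each other, so these rates of false list calls do not carry over to real lists whose genes vary together.

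The alternatives tried were the Wald test of DESeq2 1.42.0, RLE factors, scaling by total counts alone, no filter, a filter at a mean CPM of 5, library sizes without the 20 most abundant genes, each library left out in turn, only the 8 libraries compared, and the replicate letter as a replicate block. The letters are only partly shared between temperatures, and their residuals did not pair: over the 5 pairs with the same letter, the correlation across genes lay between -0.118 and 0.0675, and 3 of 10 libraries correlated best with a library of the same letter. The values with the block are therefore given in the closing section alone. The range of a list's adjusted p covers 15 alternatives by camera: RLE factors, the filter at a mean CPM of 5, the estimated correlation and each of the 12 libraries left out. After the data were seen, voom with sample quality weights and the second set of lists were added. No pair of replicates was near-identical: the chi-square per degree of freedom lay between 2.04 and 11.3 over 18 pairs.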

Results

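The transcriptome of the diatom Phaeodactylum tricornutum, a unicellular marine alga, was sequenced in cultures held in steady growth at 10, 20 and 26.5 °C, with 4 replicate cultures per temperature. The series names the 20 °C cultures as the reference, so the question was how the transcript pool of cells settled at a colder or a warmer temperature differed from it. Reads assigned to genes numbered 340541 to 405636 per library at 10 °C, 439519 to 570631 at 20 °C and 441969 to 508073 at 26.5 °C. They made up 4.02% ± 0.293 (SD, n = 4) of the reads in the 10 °C libraries, 5.01% ± 0.369 at 20 °C and 3.98% ± 0.209 at 26.5 °C. With so few reads in genes, and with the counted strand unknown, each value below is a number of reads assigned to a gene. The names of the 20 and 26.5 °C files carry a plate and those of the 10 °C files do not, so a separate library batch of the 10 °C samples cannot be told apart from their temperature.

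The libraries grouped by temperature. The first principal component of log2 CPM held 42.9% of the variance and placed the 26.5 °C libraries between those of 20 and 10 °C, and the second, with 13.3%, set the 26.5 °C libraries apart from both. The third component, with 11.3%, separated 1 library, replicate F at 20 °C, from all others. Its correlation with the other 20 °C libraries across genes lay between 0.795 and 0.801, against 0.922 to 0.937 among those 3. Light-harvesting genes took 1.10% of its gene reads (95% Wilson interval 1.07 to 1.13%), against 0.345 to 0.384% in the other 20 °C libraries, and histone genes took 0.103% (0.0944 to 0.113%), against 0.203 to 0.267%. These intervals cover counting error only. The replicate was kept in all comparisons, and values without it are given beside some of the results that moved with it.

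**Figure D1:**
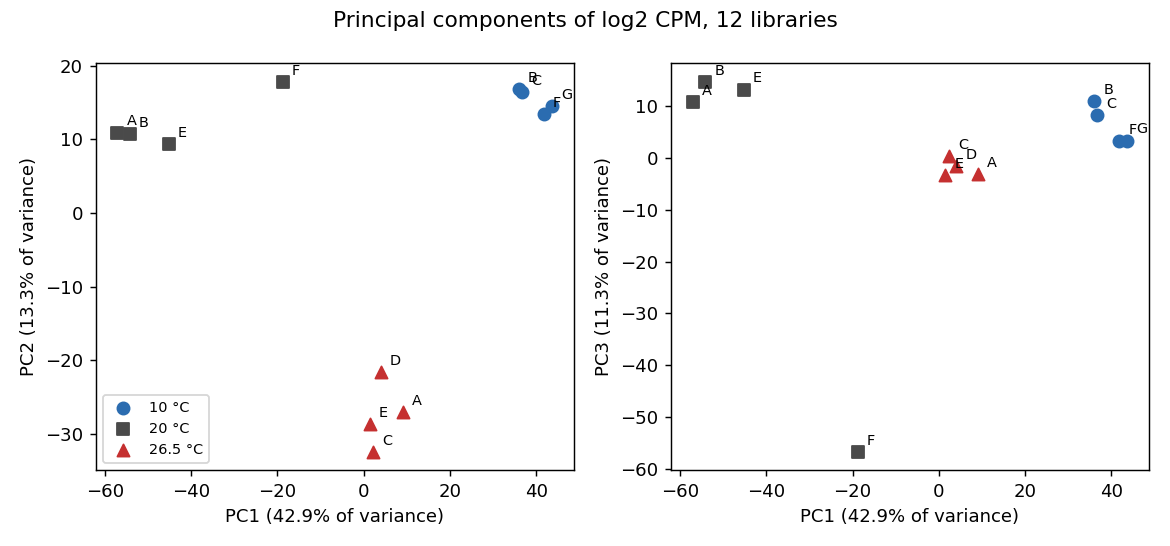
Principal components of log2 CPM for the 12 libraries, each point 1 library marked with its replicate letter; the axes are component scores and give the share of variance, 42.9% for the first, 13.3% for the second and 11.3% for the third. The 4 libraries of each temperature lie together, except replicate F at 20 °C, which has a score of -56.7 on the third component.

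At 10 °C, the ribosomal protein genes rpl2 and rps19 and the ubiquitin genes UBI1/2 and UBI3 were among the largest rises of genes with a name. A ferric reductase, a triose phosphate translocator, the cyclin gene dsCYC6 and the cyclin-dependent kinase gene hCDK6 were among the largest falls. Reads assigned to the ribosomal protein genes rpl2 (PHATR_28234) and rps19 (PHATRDRAFT_26849) rose 8.66-fold and 7.45-fold, and those of the ubiquitin genes UBI1/2 (PHATRDRAFT_22043) and UBI3 (PHATRDRAFT_27118) rose 5.71-fold and 5.48-fold. No list of ribosomal protein genes was tested. In the second set, 3 of 19 ubiquitin and ubiquitin ligase genes rose and 2 fell, values added after they were seen. Camera did not call that list (adjusted p = 0.626, and 0.906 with an estimated correlation). The rotation test fry, which does not compare a list with other genes, called it (adjusted p = 0.00714). The ferric reductase gene FRE4 (PHATRDRAFT_54409) fell 17.3-fold, from 77.6 ± 11.3 to 4.21 ± 2.87 CPM. Its level at 10 °C stands for very few reads per library, so the size of the fall is uncertain. Most core histone genes rose, and the small heat shock protein genes HSP20A and HSP20B fell. In all, 2393 of 6800 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1077 higher and 1316 lower at 10 °C, and 1803 of them changed at least 2-fold. Without replicate F at 20 °C, 3092 genes were called, 1461 higher and 1631 lower.

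The log2 fold change at 10 °C was 3.11 (SE 0.25) for rpl2, whose level was 624 ± 110 CPM at 10 °C and 72.0 ± 23.6 CPM at 20 °C. It was 2.90 (SE 0.30) for rps19, 2.51 (SE 0.27) for UBI1/2 and 2.45 (SE 0.31) for UBI3. The other largest rises were those of KCT3 (6.90-fold), the light-harvesting gene Lhcf12 (6.88-fold), FBPC1, a fructose-1,6-bisphosphatase (6.38-fold), and DHLTA_4 (4.96-fold). Among the falls, FRE4 had a log2 fold change of -4.11 (SE 0.40) and the triose phosphate translocator gene Tpt4 (PHATRDRAFT_56463) one of -4.04 (SE 0.57). The cysteine synthase gene cysK fell 8.22-fold and the cyclin gene dsCYC6, of a group specific to diatoms, 8.15-fold. The cyclin-dependent kinase gene hCDK6 fell 8.10-fold and the kinesin gene Pt-KIF3 7.96-fold. The level of hCDK6 at 10 °C, 6.58 ± 7.60 CPM, also stands for very few reads per library. Lhcf15, another light-harvesting gene, fell 7.75-fold and ODC3, an ornithine decarboxylase, 7.66-fold. Adjusted p values of these 16 genes in the quasi-likelihood test lay between 1.1e-08 and 0.000861; the genes were chosen for CPM values that do not overlap between the 4 libraries at 10 °C and the 4 at 20 °C. Tpt4 had 2827 CPM in replicate F at 20 °C and 260 to 535 CPM in the other 3, and without replicate F its log2 fold change was -2.72. Without replicate C at 10 °C the log2 fold changes of hCDK6 and Lhcf15 were -4.14 and -3.73, against -3.02 and -2.95 with all libraries, and without replicate B at 20 °C that of FBPC1 was 3.29, against 2.67.

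**Figure D2:**
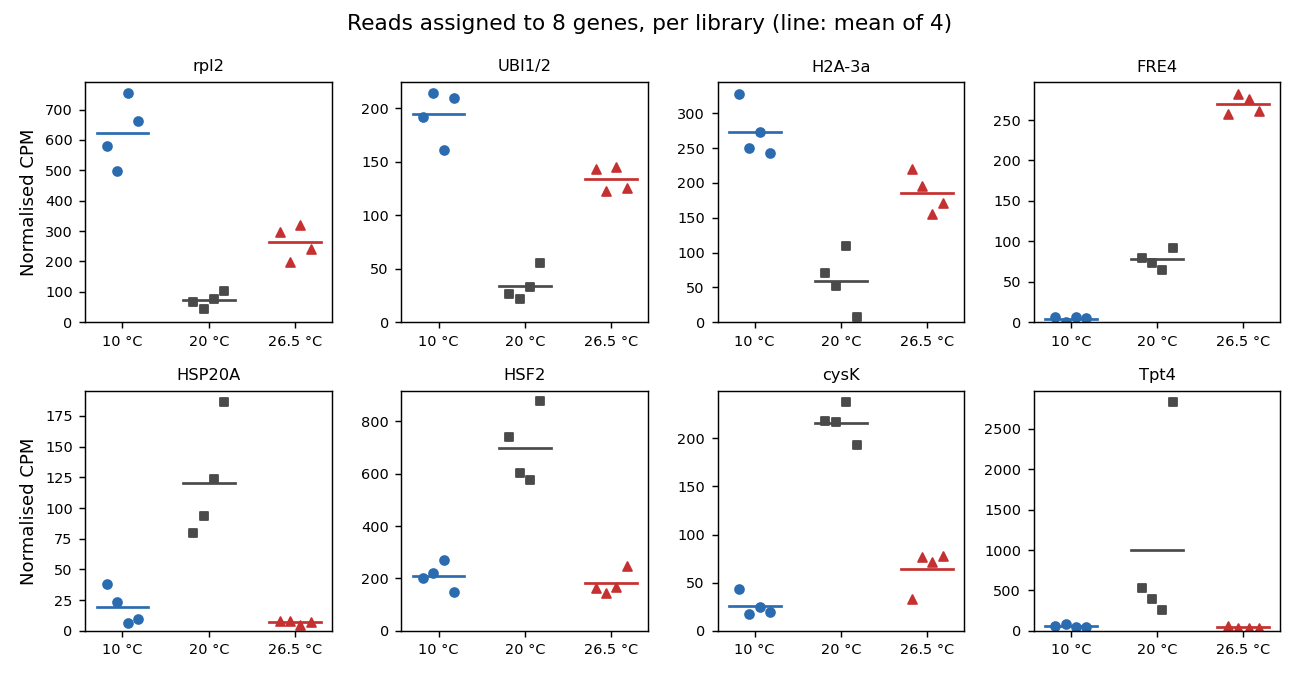
Normalised CPM of reads assigned to 8 genes, each point 1 library and each line the mean of 4; every vertical axis is linear and starts at 0. FRE4 is lowest at 10 °C (4.21 CPM on average) and highest at 26.5 °C (269 CPM), while rpl2, UBI1/2 and H2A-3a are lowest at 20 °C and HSP20A, HSF2, cysK and Tpt4 are highest there.

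Histones, the proteins that package DNA, were the only one of the 6 gene lists called at 10 °C. At least 1 list was called in 35 of 35 ways to split the libraries at 10 and 20 °C into 4 and 4. The number of lists called therefore does not set the real grouping apart. Of 13 histone genes, 10 rose and none fell over all genes tested by edgeR or DESeq2, none being lower even at an unadjusted p under 0.05, and 11 rose adjusted over the list alone. H2A-3a rose 4.49-fold, H2B-1a 3.65-fold and H2A-3b 3.57-fold, and the median log2 fold change of the list was 1.65. The variant H3.3 had a log2 fold change of -0.31 without a call. The list's adjusted p by camera was 3.3e-05, and the call was lost at an adjusted p = 0.597 with an estimated correlation, the highest over the 15 alternatives by camera, of which the lowest was 1.4e-06. In replicate F at 20 °C histone genes took the smallest share of gene reads among the 12 libraries. Without it 11 rose and H3.3 fell, but the rises were smaller. The median log2 fold change of the list was then 1.34, and H2A-3a rose 3.46-fold and H2A-3b 2.72-fold. Voom with quality weights, which gave replicate F a low weight, called 11 higher and 1 lower.

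Of 32 light-harvesting genes, which encode the fucoxanthin and chlorophyll proteins of the antenna, 4 rose and 1 fell at 10 °C; adjusted over the list alone, 2 rose and 1 fell. Beside Lhcf12 and Lhcf15 they included Lhcx1, a gene of the group linked to photoprotection, which rose 2.85-fold. The list as a whole was not called (adjusted p = 0.0592, and adjusted p = 0.855 with an estimated correlation, the highest of 15 alternatives by camera). The group depended on replicate F at 20 °C, in which light-harvesting genes took 1.10% of gene reads: without it, 20 members rose and 1 fell, the adjusted p of the list was 9.0e-06, the lowest of the alternatives, and Lhcx1 rose 6.40-fold. Without replicate B at 10 °C the list was also called, at an adjusted p of 0.0181. Leaving out replicate A, B or E at 20 °C, or replicate F at 10 °C, left 2 members with a rise, and without replicate A or B at 20 °C or replicate C at 10 °C, or with a filter at a mean CPM of 5, 2 members fell.

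Chaperone genes went both ways. Of 14 tested, 2 rose and 4 fell at 10 °C, both over all genes and adjusted over the list alone. The small heat shock protein genes HSP20A and HSP20B fell 6.25-fold and 2.86-fold, and Hsp70_2 fell 1.94-fold, while the chaperonin gene CPN60_2 rose 3.77-fold and HSP40C 2.67-fold. The list was not called (adjusted p = 0.788, and adjusted p = 0.878 with an estimated correlation, the highest of 15 alternatives by camera, of which the lowest was 0.514); its median log2 fold change was 0.04, its mean -0.25 and the direction of the test downward. Without replicate F at 20 °C, 6 rose and 3 fell, the direction of the test was upward without a call, and CPN60_2 rose 5.92-fold. HSF2, a heat shock transcription factor gene, fell with a log2 fold change of -1.73 (SE 0.23), and HSF1 and HSF3 had log2 fold changes of 0.20 and -0.23 without a call.

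In the lists of DNA replication and cell cycle genes fixed beforehand, MCM4 and CDKA1 were the calls at 10 °C. Of 5 DNA replication genes, 1 fell in both adjustments, the helicase subunit gene MCM4, with a log2 fold change of -1.19 that was no longer called without replicate A at 20 °C (-0.85). Of 6 cell cycle genes, 1 fell in both adjustments, the cyclin-dependent kinase gene CDKA1, which fell 1.88-fold. The log2 fold change was above 0 for 5 of the 6, with a median of 0.30, and the direction of the test was upward. Of 14 vesicle traffic genes, 4 rose and 1 fell, and adjusted over the list alone 5 rose and 1 fell. Sec23, a subunit of the COPII vesicle coat, rose 1.74-fold, a call that was lost without replicate C at 10 °C (log2 fold change 0.64 there, 0.80 with all libraries), and Sec7C fell 2.25-fold. Without replicate G at 10 °C 2 vesicle traffic genes rose, and without replicate F at 20 °C 2 fell. Camera called none of these 3 lists. For DNA replication the adjusted p was 0.664 (0.465 to 0.855 over 15 alternatives by camera), for the cell cycle 0.788 (0.602 to 0.890) and for vesicle traffic 0.374 (0.220 to 0.832). The rotation test fry, which does not compare a list with other genes, called vesicle traffic alone of the 3, with an adjusted p of 0.0320. With an estimated correlation these adjusted p values were 0.855, 0.878 and 0.832.

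At 26.5 °C, the warm side of the same 20 °C reference, rps19, UBI1/2 and rpl2 were again among the largest rises, up 4.03-fold, 3.94-fold and 3.67-fold. Of the 19 ubiquitin and ubiquitin ligase genes, 3 rose and 1 fell. Camera did not call that list (adjusted p = 0.296, and 0.975 with an estimated correlation), and fry did (adjusted p = 0.00892). Heat shock genes were among the largest falls. HSP20A fell 16.3-fold, from 121 ± 47.3 to 7.08 ± 1.82 CPM, a level of only a few reads per library. HSP20C fell 4.96-fold and the heat shock factor gene HSF2 (PHATRDRAFT_55070) 3.85-fold. FRE4 rose 3.47-fold, to 269 ± 12 CPM. The quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment called 1321 of 6800 genes, 580 higher and 741 lower at 26.5 °C, and 938 of them changed at least 2-fold. Once replicate F at 20 °C was left out it called 2106, 995 higher and 1111 lower.

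The log2 fold change at 26.5 °C was 2.01 (SE 0.30) for rps19, 1.98 (SE 0.27) for UBI1/2, 1.88 (SE 0.25) for rpl2 and 1.80 (SE 0.24) for FRE4. The other largest rises were those of Lhcf12 (3.93-fold), KCT3 (3.59-fold), Fru3 (3.53-fold) and GAPDH_3, a glyceraldehyde-3-phosphate dehydrogenase gene (3.36-fold). Tpt4 fell 23.1-fold and the light-harvesting gene Lhcx2 13.4-fold. HSP20A had a log2 fold change of -4.03 (SE 0.46), HSP20C one of -2.31 (SE 0.66) and HSF2 one of -1.95 (SE 0.23). The remaining falls were those of hCDK6 (6.85-fold), APC8, a gene of the anaphase-promoting complex (4.53-fold), and Sit4 (3.84-fold). The level of hCDK6 at 26.5 °C, 7.43 ± 5.33 CPM, stands for a few reads per library. Adjusted p values of these 16 genes lay between 3.9e-06 and 0.0165 in the quasi-likelihood test; they were chosen, as at 10 °C, for CPM values without overlap between the groups. Replicate F at 20 °C held 253 CPM of Lhcx2 and 2827 CPM of Tpt4, above the other 3 libraries at 20 °C, and without it these genes had log2 fold changes of -2.27 and -3.20. It also held 108 CPM of HSP20C, against 33.9 to 39.8 CPM in the other 3, and without it HSP20C had a log2 fold change of -1.79.

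Of the 6 lists, histones and light-harvesting proteins were called at 26.5 °C with the preset correlation, and neither with an estimated one or by fry. As many lists were called in 23 of 35 ways to split the libraries at 26.5 and 20 °C into 4 and 4, the real one included. Of 13 histone genes 7 rose and none fell by edgeR, none being lower at an unadjusted p under 0.05, and 10 rose adjusted over the list alone, with H2A-3a up 3.05-fold, H3-1a up 2.78-fold and a median log2 fold change of 1.11. The adjusted p of the histone list was 3.8e-05, against an adjusted p = 0.610 with an estimated correlation, the highest of 15 alternatives by camera, and 5.4e-07 as the lowest. Leaving out single libraries gave 5 to 9 histone genes with a rise, and H3.3 fell without replicate F at 20 °C, where the histone share of gene reads was lowest. Without that replicate the rises were smaller, with a list median of 0.79, H2A-3a up 2.36-fold and H3-1a up 2.17-fold. Voom with quality weights called 9 higher and 1 lower.

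Of 32 light-harvesting genes at 26.5 °C, 2 rose and 2 fell, and adjusted over the list alone 2 rose and 1 fell. Lhcf5 rose 2.50-fold and Lhcf12 3.93-fold, and Lhcx2 fell 13.4-fold. The adjusted p of the list was 0.00852, with a median log2 fold change of 0.22, and adjusted p = 0.612 with an estimated correlation, the highest of 15 alternatives by camera, the lowest being 1.6e-08 without replicate F at 20 °C. Without that replicate, in which light-harvesting genes took 1.10% of gene reads, 22 members rose and 4 fell; Lhcf5 then rose 3.96-fold. The call of the list was lost without replicate B at 20 °C (adjusted p = 0.0662) and without replicate E at 20 °C (adjusted p = 0.138). Leaving out replicate A or E at 20 °C, or replicate A or C at 26.5 °C, left 1 member with a fall.

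**Figure D3:**
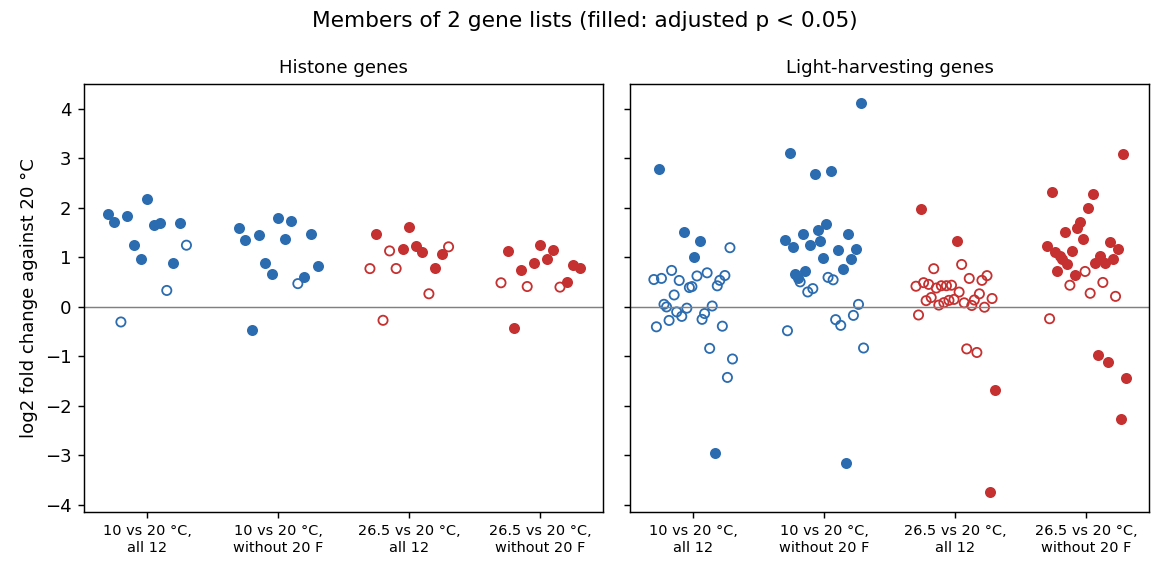
Log2 fold changes against 20 °C (vertical axis) of the 13 histone genes and the 32 light-harvesting genes, each point 1 gene, filled where it was called, with all 12 libraries and without replicate F at 20 °C. The light-harvesting genes with a rise number 4 and 2 with all libraries at 10 and 26.5 °C, and 20 and 22 without that replicate.

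Chaperone genes fell more often than they rose at 26.5 °C. Of 14 tested, 6 fell and 1 rose, over all genes and adjusted over the list alone. All 4 small heat shock protein genes of the list fell: beside HSP20A and HSP20C, HSP20B fell 3.37-fold and HSP20 fell from 38.0 ± 12.8 to 13.1 ± 4.75 CPM. HSP20A, HSP20B and HSP20C stayed called with any single library left out, HSP20C at an adjusted p of up to 0.0482 by edgeR. HSP20 lost its call without replicate C at 26.5 °C. The rise was that of CPN60_2 (2.52-fold, and 3.95-fold without replicate F at 20 °C). The list was not called (adjusted p = 0.332, with 0.159 to 0.818 over 15 alternatives by camera and 0.644 with an estimated correlation). Without replicate F at 20 °C, 3 rose and 5 fell and the direction of the test was upward without a call; without replicate A, C or E at 26.5 °C, 4, 3 and 4 fell, and without replicate A at 20 °C 2 rose.

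MCM4 and MCM2, of the 5 DNA replication genes, fell at 26.5 °C in both adjustments, with log2 fold changes of -1.26 and -1.24. The call of MCM4 was lost without replicate A at 20 °C (-0.92), and that of MCM2 without replicate A at 20 °C or replicate A, C or D at 26.5 °C; the lowest and highest values for MCM2 with 1 library left out were -1.41 and -0.97. The list's median log2 fold change was 0.20, its mean -0.32 and the direction of the test downward. None of 6 cell cycle genes was called in either adjustment by edgeR, nor by DESeq2, voom with quality weights called 1 lower, and 1 had an unadjusted p under 0.05 in edgeR; CDKA1 had a log2 fold change of -0.28. Leaving out replicate F at 20 °C gave 1 that fell. Of 14 vesicle traffic genes 3 rose and 1 fell in both adjustments, among them Sec23, which rose 1.69-fold. The call of Sec23 was lost without replicate A, B or E at 20 °C or replicate A or C at 26.5 °C, with log2 fold changes from 0.66 to 0.89 when single libraries were left out. No vesicle traffic gene rose without replicate B or E at 20 °C or replicate A or C at 26.5 °C, and 1 rose without replicate A at 20 °C, E at 26.5 °C, or B or F at 10 °C. With RLE factors 1 rose and 1 fell, and with a filter at a mean CPM of 5 1 rose and none fell by edgeR. The fall was that of Sec7C, with a log2 fold change of -0.54, and its call was lost without replicate A or E at 20 °C, any of the 4 libraries at 26.5 °C, or replicate B or C at 10 °C. None of these 3 lists was called by camera or by fry. For DNA replication the adjusted p was 0.485 (0.358 to 0.754 over 15 alternatives by camera), for the cell cycle 0.332 (0.256 to 0.618) and for vesicle traffic 0.332 (0.277 to 0.612). With an estimated correlation these adjusted p values were 0.644, 0.612 and 0.612.

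Libraries at 10 and at 26.5 °C differed from those at 20 °C largely in the same direction. The 20 °C libraries also had a larger share of reads in genes, 5.01% on average, against 4.02% at 10 °C and 3.98% at 26.5 °C. Ribosomal protein genes rpl2 and rps19, UBI1/2, Lhcf12, KCT3 and CPN60_2 were higher at both temperatures than at 20 °C, and Tpt4, hCDK6, cysK, HSP20A, HSP20B and HSF2 were lower at both. Of 1057 genes called in both comparisons, 444 were higher at both temperatures, 601 lower at both, none higher at 10 °C and lower at 26.5 °C, and 12 lower at 10 °C and higher at 26.5 °C, so that 98.9% moved the same way. For the empty class, higher at 10 °C and lower at 26.5 °C, edgeR gave 3 genes at unadjusted p values under 0.05, DESeq2 0 and voom with quality weights 2. FRE4, which encodes a ferric reductase, was the 1 gene with a symbol among those 12, and was ordered with temperature.

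The comparisons share the 20 °C libraries, which by itself makes their fold changes correlate. Lists of these sizes drawn independently would share 91.9 genes higher and 143 lower at both temperatures, and 117 and 112 in the opposite directions. The covariance of the log2 fold changes across genes, which are not independent replicates, was 0.667, against 0.0975 on average in 50 simulated sets without any temperature effect, of which the highest was 0.104. The correlation of the log2 fold changes was 0.733, against 0.553 on average (0.529 to 0.576) in the simulated sets, where only the shared libraries could give it. Over the 6 ways to part the 20 °C libraries it was 0.506 to 0.615. The simulated sets held at most 1 gene called in both comparisons. Their genes were drawn independently of each other, so these ranges could be wider for genes that vary together. With the 20 °C libraries parted so that the comparisons shared none, 516 to 761 genes were called in both over the 6 ways, and 96.3 to 98.9% of them moved the same way. Without replicate F at 20 °C, 1732 genes were called in both, 784 higher and 925 lower at both temperatures.

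The direct comparison of 26.5 with 10 °C tested where the effects of cold and warmth differed. FRE4 differed most of the named genes, with a log2 fold change of 5.91 (SE 0.37), from 4.21 ± 2.87 to 269 ± 12 CPM. With 340541 to 405636 gene reads per library at 10 °C, 4.21 CPM stands for very few reads, so the size of this change is uncertain. The kinesin gene Pt-KIF3 (log2 fold change 2.04), Lhcf15 (2.03), ODC3 (1.89) and the cyclin gene dsCYC6 (1.80) were higher at 26.5 °C, and rpl2 (-1.24) and H2B-1a (-1.10) were lower. These 7 genes stayed called when single libraries were left out, and their adjusted p values in edgeR lay between 1.5e-09 and 0.0129. The other genes named by the rule and called here were rps19, UBI3, cysK, FBPC1, CDKA1 and Sec7C. Their calls were less stable and were lost in 3 (FBPC1) to 9 (UBI3) of the 12 fits with 1 library left out. Without replicate C at 10 °C the value for Lhcf15 was 2.80. In all, edgeR's quasi-likelihood test called 752 genes, 471 higher and 281 lower at 26.5 °C, of which 543 differed at least 2-fold. The count was 1333 without replicate F at 20 °C, 774 higher and 559 lower, and 490 without replicate C at 26.5 °C, 160 of them lower; without replicate E at 26.5 °C 178 were lower. Of the 1045 genes that moved the same way against 20 °C at both temperatures, 225 were called in this comparison.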

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

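The tests of a wrong label, of sequencing depth, of a library batch at 10 °C and of the counted strand were chosen only after the results they measure had been seen. A library was singled out when its gap to the nearest other library of its temperature was large against the range of the 4. In groups of 4 chance does this in about 1 of 20, which for 120 groups gives 6, and 8 were found, 7 of them in replicate F at 20 °C. The values of different genes in 1 library are not independent of each other.

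Replicate F at 20 °C had a mean correlation of 0.798 with the other libraries of its temperature, while those had 0.885 to 0.888 with F included. It held 455 CPM of Lhcx1 (71.9 to 75.6 CPM in the other 3), 253 CPM of Lhcx2 (17.9 to 46.3), 198 CPM of Lhcf16 (19.9 to 29.1) and 2827 CPM of Tpt4 (260 to 535), and also 108 CPM of HSP20C (33.9 to 39.8) and 172 CPM of Sec23 (116 to 123). The tables argue against a 10 or 26.5 °C library under the label 20 °C, since its highest mean correlation with either was 0.802, below 0.885, the lowest mean of any other library with its own group; against depth, since its 451882 gene reads lie within the range of the other 3; and against a few abundant genes, since without the 200 most abundant the correlation was 0.746, where the lowest mean of any other library with its own group was 0.855. The 0.802 was its mean correlation with the 26.5 °C libraries, slightly above the 0.798 with its own group. Reads in no annotated gene made up 87.3% of its reads, against 84.7 to 85.5% in the other 20 °C libraries. Reads without a unique position made up 8.16%, against 9.47 to 9.89%. Both values lie inside the ranges of the 26.5 °C libraries, 87.1 to 88.4% and 7.76 to 8.88%. A culture in another state or a library prepared differently could both give this, and these values do not separate them. The labels name no condition that sets this culture apart, and no biological explanation was tested.

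Genes called at both temperatures moved the same way in 98.9% of cases. The shared 20 °C libraries as the sole source are argued against by the comparisons that share none, with a lowest covariance of 0.523. Simulated sets without any effect, which did share them, reached 0.104. Their genes were drawn independently, so genes that vary together could give a wider range. Without replicate F, 98.7% of the genes called in both still moved the same way, so the pattern did not need that library. Those comparisons still share the other 20 °C libraries, which favours the same direction, so this share alone is a weak test. A library batch of the 10 °C samples may have moved genes at 10 °C but gives no reason for the 26.5 °C libraries to move with them. The libraries also differed in make-up. Reads in no annotated gene averaged 85.6% at 20 °C, 87.9% at 26.5 °C and 89.2% at 10 °C. Reads without a unique position averaged 9.34, 8.15 and 6.79% in the same order. Whether such differences between libraries moved genes the same way was not tested. It also stays open whether the 3 other 20 °C cultures differ from the rest by temperature alone. A response to both sides of 20 °C is a hypothesis that these data cannot test further.

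Few reads were assigned to genes, with a median of 88.0% in no annotated gene. Counting on the strand opposite to the transcripts could give this, and so could reads from sequence outside the annotated genes. In opposite-strand counting, reads of a gene would appear on an overlapping neighbour: the 17 genes overlapped by more than 200 bases had 2.19 times the median CPM per kb of the 472 overlapped by less (a two-sided permutation p = 0.01). The reference table gives no strand, so the overlaps cannot be sorted into opposite and same strand, and these explanations cannot be told apart. Under the first, the values of a named gene would describe transcripts from the other strand at its place.

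HSP20B in replicate E at 20 °C had 601 CPM against 703 to 721 CPM in the other 3 libraries.

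The real grouping gave the most calls for each count over all genes tested that was set against other splits of the libraries. The other splits mix libraries of different temperatures in a group, which widens the spread and lowers their calls. With 35 splits the smallest share possible is 1 of 35. This ranking therefore does not exclude chance, and it does not tell temperature from a library batch. Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave as many genes between 10 and 20 °C (2393, highest other 274), between 26.5 and 20 °C (1321, highest other 188) and between 26.5 and 10 °C (752, highest other 0). For changes of at least 2-fold the real split was again 1 of 35, with 1803 against 267 and 938 against 179. Of 100 assignments of the 12 libraries, 1, the real one, gave as many genes called in both comparisons (1057, highest other 18). The other splits with most calls against 20 °C exchanged replicate F at 20 °C for a library of the other temperature, which shows a structure of the samples. The number of gene lists did not set the real split apart: 35 of 35 splits gave at least the 1 list called at 10 °C (highest other 4) and 23 of 35 at least the 2 called at 26.5 °C (highest other 4).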

How the results depend on the processing

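Voom with quality weights was chosen after the data were seen. No count over all genes tested changed its balance of directions by 10 points or more under another scaling, and no named gene reversed. Of 88 values for named genes, 87 kept their call under DESeq2, 86 under RLE factors, 86 under total counts alone, 88 under voom with quality weights and 57 with the replicate block; 84 of 87 kept it with only the 2 temperatures compared. The cause of the changes below was not tested except where fewer libraries or degrees of freedom give it. With the replicate block, which leaves fewer degrees of freedom, 1348 genes were called at 10 against 20 °C, 666 at 26.5 against 20 °C, 112 at 26.5 against 10 °C and 474 in both comparisons. Voom with quality weights, which gave replicate F at 20 °C a weight of 0.231, called 2102 genes at 26.5 °C and 1680 in both comparisons. With only the 2 temperatures compared, 1244 genes were called at 26.5 against 10 °C, and with the 20 °C libraries parted a mean of 634.3 over 6 ways in both comparisons. Leaving out single libraries gave 2008 to 3092 genes at 10 °C (2-fold 1626 to 2319), 946 to 2106 at 26.5 °C (2-fold 774 to 1373), 490 to 1333 at 26.5 against 10 °C and 758 to 1732 in both, each highest value without replicate F at 20 °C. Of these, the counts at 10 °C and all 2-fold counts stayed within 1.5 times. Of the gene lists, camera with the correlation estimated per list called 0 at 10 °C and 0 at 26.5 °C, with 0 at an unadjusted p under 0.05, and fry called 2 and 0, where camera with the preset correlation called 1 and 2. With the filter at a mean CPM of 5, a further list, photosystem and electron transport genes, had enough members for a test and was called at 26.5 °C (adjusted p = 0.0376), which made 3 lists, and not at 10 °C (adjusted p = 0.0689). Leaving out single libraries gave 1 to 2 lists in each comparison: 2 at 10 °C without 20 °C replicate F or 10 °C replicate B, and 1 at 26.5 °C without 20 °C replicate B or E. The counts over all genes tested stayed within 1.5 times under DESeq2, RLE factors, total counts alone, no filter, a filter at a mean CPM of 5 and without the 20 most abundant genes. Counts within lists moved more, also in their balance: of the vesicle traffic genes, 3 rose and 1 fell at 26.5 °C with TMM, 1 rose and 1 fell with RLE factors and 1 rose with the filter at a mean CPM of 5, and of the light-harvesting genes 2 in place of 1 fell at 10 °C with that filter. In the simulated data, 34.0% of 2-fold changes at 10 °C were recovered; depth, number of libraries and spread were not varied.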

Other observations

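The second set of gene lists was written after the reference symbols had been seen, and the lists described here were chosen from it after their values had been seen. Cyclin-dependent kinase genes that were called fell. Of 9 such genes, 4 fell and none rose at 10 °C by edgeR, DESeq2 or voom with quality weights, among them hCDK6 and CDKA1, and 4 fell with any single library left out. At 26.5 °C 1 fell, and 2 without replicate F at 20 °C. Of 13 cyclin genes, 3 fell at 10 °C, dsCYC6, dsCYC3 and dsCYC11, and 1 fell at 26.5 °C. Only 1 cyclin gene fell at 10 °C without replicate A, B or E at 20 °C or replicate B at 10 °C, and 2 fell at 26.5 °C without replicate F at 20 °C. Camera called neither list (adjusted p 0.456 and 0.703 at 10 °C, 0.5998 for each at 26.5 °C). Fry, which does not compare a list with other genes, called the kinases (adjusted p 0.00714 and 0.0467) and not the cyclins (0.387 and 0.609).

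Most genes of the lists of adaptins and of coat and Sec proteins were not called. Of 13 adaptin and clathrin genes, 4 rose and 1 fell at 10 °C and 3 rose at 26.5 °C. AP4sigma, a subunit of an adaptor complex, rose 4.48-fold and 3.17-fold (adjusted p by edgeR's quasi-likelihood test 0.000132 and 0.00379), and the clathrin heavy chain gene CHC had a log2 fold change of -0.74 at 10 °C. Of 12 genes of COPI and COPII coat and Sec proteins, 4 rose and 1 fell at 10 °C and 3 rose and 1 fell at 26.5 °C, with COPIepsilon up 2.59-fold and 2.34-fold. Leaving out replicate A, B or E at 20 °C, or replicate A or C at 26.5 °C, left 1 gene of this list with a rise at 26.5 °C; the fall, that of Sec7C, was lost without 8 of the 12 libraries, and with RLE factors or total counts alone 2 rose. Camera called neither list: the adjusted p was 0.341 and 0.138 for adaptins and clathrin and 0.342 and 0.245 for coat and Sec proteins, and 0.906 at 10 °C and 0.975 at 26.5 °C for each with an estimated correlation. Fry called both (adjusted p 0.00714 and 0.00892, and 0.0132 and 0.0216).

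Genes of nitrogen and amino acid metabolism numbered 23, of which 7 rose and 2 fell at 10 °C, and 6 rose and 2 fell at 26.5 °C. Without replicate F at 20 °C 11 rose at 10 °C, and 1 fell at 26.5 °C without replicate A or B at 20 °C or replicate A, C or E at 26.5 °C. METH rose 2.40-fold at 26.5 °C. Of 12 genes of fatty acid synthesis, 5 rose and 1 fell at 10 °C. The number that rose was 1 without replicate A at 20 °C, 2 without replicate B or E at 20 °C or B or G at 10 °C, and 3 without replicate C or F at 10 °C. At 26.5 °C 2 of these genes rose and 1 fell; 4 rose without replicate F at 20 °C, and 1 rose without any other 20 °C library, any 26.5 °C library, or replicate B or F at 10 °C. The fall, that of ACC1, was lost without replicate A, D or E at 26.5 °C. The acetyl-CoA carboxylase gene ACC1 fell by 0.76 on the log2 scale at 10 °C. Camera called neither list with all libraries (adjusted p 0.281 and 0.296 for nitrogen, 0.188 and 0.5998 for fatty acid synthesis), and called fatty acid synthesis at 10 °C without replicate F at 20 °C. With all libraries and an estimated correlation, its adjusted p for fatty acid synthesis at 10 °C was 0.906. Fry called the nitrogen list (adjusted p 0.00714 and 0.0431) and not fatty acid synthesis (0.0514 and 0.541).

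Of 17 genes of the Lhcf group of light-harvesting proteins, 3 rose and 1 fell at 10 °C and 2 rose at 26.5 °C. Without replicate F at 20 °C 13 rose and 1 fell at 10 °C and 14 rose and 1 fell at 26.5 °C; without replicate A, B or E at 20 °C or F at 10 °C, 1 rose at 10 °C. Camera with the preset correlation called 1 of the 39 lists at 10 °C, the histones, and 2 at 26.5 °C, the histones and the Lhcf group (adjusted p = 0.0165 for the latter, and 0.975 with an estimated correlation). The call of the Lhcf group was lost without replicate B (adjusted p = 0.148) or E at 20 °C (adjusted p = 0.188), the range over left-out libraries being 1.1e-07 to 0.188. With the correlation estimated per list camera called 0 in either comparison, with 0 at an unadjusted p under 0.05, and fry called 9 in each. Without replicate F at 20 °C camera called 3 in each: histones, the Lhcf group and fatty acid synthesis at 10 °C, and histones, the Lhcf group and the Lhcr group at 26.5 °C.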
